A study of Homo sapiens with 26 samples.

How the data were processed

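Gene expression was measured in MDA-MB-468, an established human breast cancer cell line of the basal, triple-negative type, on 26 Affymetrix HG-U133 Plus 2.0 arrays in 2 experiments. Per the labels, RNA was converted to cRNA and labelled with biotin by the array maker's methods. The deposited table holds 1 value per probe set and array on a linear intensity scale, which ranged from 7.12 to 32597. RMA and R 2.10 are named in the submitters' processing notes, with no roles given. RMA corrects background, makes the distributions of the arrays alike and summarises the probes of a probe set, so a change that moved most transcripts 1 way would be reduced. It gives no detection calls. The analysis plan, written before the data were examined, assumed log2 values. The deposited intensities were therefore converted to log2 and the planned test was kept.

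Array medians of log2 intensity lay between 7.60 and 7.65 in the antagonism experiment and between 6.84 and 6.88 in the agonism experiment. Sorted values matched closely within each experiment and not between them, so levels were not compared between experiments. Whether the authors normalised the 2 experiments separately is not given in the sources used here. Tests were made within an experiment, and the only values taken across were differences or correlations of within-experiment changes.

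Of 54675 probe sets, 62 were controls. The platform annotation gave 41091 probe sets with 1 gene symbol, 1801 with several and 11777 with none, the last number including the controls. For 41037 of the single-gene probe sets the gene ID was matched to the reference gene table (assembly GRCh38.p14, used for names only), and 0 symbols changed. Each gene was represented by its single-gene probe set with the highest mean over all arrays, which gave 19775 genes. Of these, 9252 had 1 probe set and 10523 had more than 1. Probe sets ending in _x_at or _s_at can also detect related transcripts. No gene was left out for low intensity. The table held 0 columns of other samples. Some members of the fixed gene lists are not analysed here, and each list's count is over its measured members.

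Groups were taken from the treatment labels. The antagonism experiment had 3 control arrays, 3 DAPT arrays and 2 anti-NOTCH3 A4 arrays. The agonism experiment had 3 arrays in each of 6 groups. The labels give no replicate numbers, so the arrays of a group are numbered here in the order in which they are listed. The labels also give no batches or dates, and do not say that the arrays of a group came from separate cultures. For the agonism experiment the protocol speaks of a single DMSO plate. The p-values therefore measure the spread between these samples, which may be technical. The SD of the log2 difference between 2 arrays of a group was 0.32 for antagonism controls 2 and 3, and 0.13 for DAPT arrays 1 and 2 of the same experiment. The number of arrays limits the precision. The median standard error of a log2 change was 0.088 for DAPT in the antagonism experiment and 0.081 in the agonism experiment.

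Changes were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, no trend, not robust), with every group of an experiment in 1 fit. The residual degrees of freedom were 5 in the antagonism experiment and 12 in the agonism experiment, and 17 for the difference of the DAPT effects, fitted over all arrays. P-values were adjusted by Benjamini-Hochberg over all genes, and a gene passed at an adjusted p under 0.05. Every adjusted p printed is from limma. A rise or fall is a log2 change that passed, and each printed change is a log2 difference of group means with its standard error (SE). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

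The 20 gene lists were fixed before the data were examined. Each was tested in each of 11 comparisons with limma's camera at a preset inter-gene correlation of 0.01, adjusted over all lists and comparisons, with an estimated correlation and fry beside it. Of 75 list calls with the preset correlation, 8 held with an estimated correlation. These were the canonical Notch targets on washout against DAPT, with A13, and in the difference of the agonist effects; the MYC and ribosome biogenesis list with A13; the interferon list with A13 and with JAG1; and the NF-kB and immediate early lists with Fc beads. Among genes above the median level, with an estimated correlation, only the Notch targets in the difference of the agonist effects kept their call (adjusted p = 0.0258), and the other 7 were lost. Fry, which tests whether a list's genes move on balance 1 way and does not compare them with other genes, made 83 calls.

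Named genes followed a rule fixed in advance. For each comparison these were the 12 largest rises and 12 largest falls among passing genes whose arrays did not overlap between the groups, every canonical Notch target, up to 4 passing members of each other list, and NOTCH1, NOTCH2, NOTCH3, NOTCH4, JAG1 and MYC. Where fewer than 5 genes passed, the 5 with the smallest p were taken. For the differences of effects the overlap condition and the members of other lists were left out. Not every gene that the rule allows is printed.

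The fit was tested on simulated data with 200 of 19775 genes changed. Each gene and array was drawn independently, without the array-wide deviations that the antagonism controls show. The shares and false calls below therefore need not hold for the real arrays. For DAPT in the antagonism experiment it recovered 58.2% of genes changed by 0.5 on the log2 scale and 97% of those changed by 1. For A4 the shares were 49.3% and 91%, for A13 95.5% and 100%, and for the difference of the agonist effects 56.7% and 97%. False calls were 14 of 184 for DAPT, 9 of 169 for A4, 11 of 208 for A13 and 12 of 181 for the difference, each more than 5% of the calls. Camera found the 1 shifted list, and also called 1 of 19 unshifted lists.

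Alternative settings were repeated quantile normalization, median centring, genes above the median level only, the mean of all probe sets of a gene, no probe sets ending in _x_at or _s_at, a trended and robust variance, array weights, a fit to the compared groups only, a fit to all 26 arrays, and leaving out each array in turn. Alternatives chosen after seeing the data were the upper quartile of each array as a covariate, and leaving out antagonism controls 2 and 3 together. Correlations of changes are across genes, which are not independent replicates.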

Results

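Both experiments asked what NOTCH3 signalling does to gene expression in MDA-MB-468 cells. NOTCH3 is a cell-surface receptor whose signal needs cleavage by gamma-secretase. In the antagonism experiment cells grew for 40 h and were then treated for 24 h. They received a control IgG (10 µg/ml) with 0.05% DMSO, the same IgG with the gamma-secretase inhibitor DAPT (5 µM), or the NOTCH3 antibody A4 (10 µg/ml) with 0.05% DMSO. In the agonism experiment all plates but the DMSO plate had 5 µM DAPT for 16 h, followed by 2 h in plain medium. The washed plates then received DAPT again, a control IgG (20 µg/ml), the NOTCH3 antibody A13 (20 µg/ml), beads coated with Fc, or beads coated with JAG1-Fc, a Notch ligand. DMSO or DAPT was added again to its own plates at 22 h, and all arrays analysed here are labelled as harvested at 24 h. Every group had 3 arrays except A4, which had 2, so that 8 of the 26 arrays belonged to the antagonism experiment and 18 to the agonism experiment. Each array gave 1 intensity per probe set, and 19775 genes were tested with 1 probe set each.

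**Figure D1:**
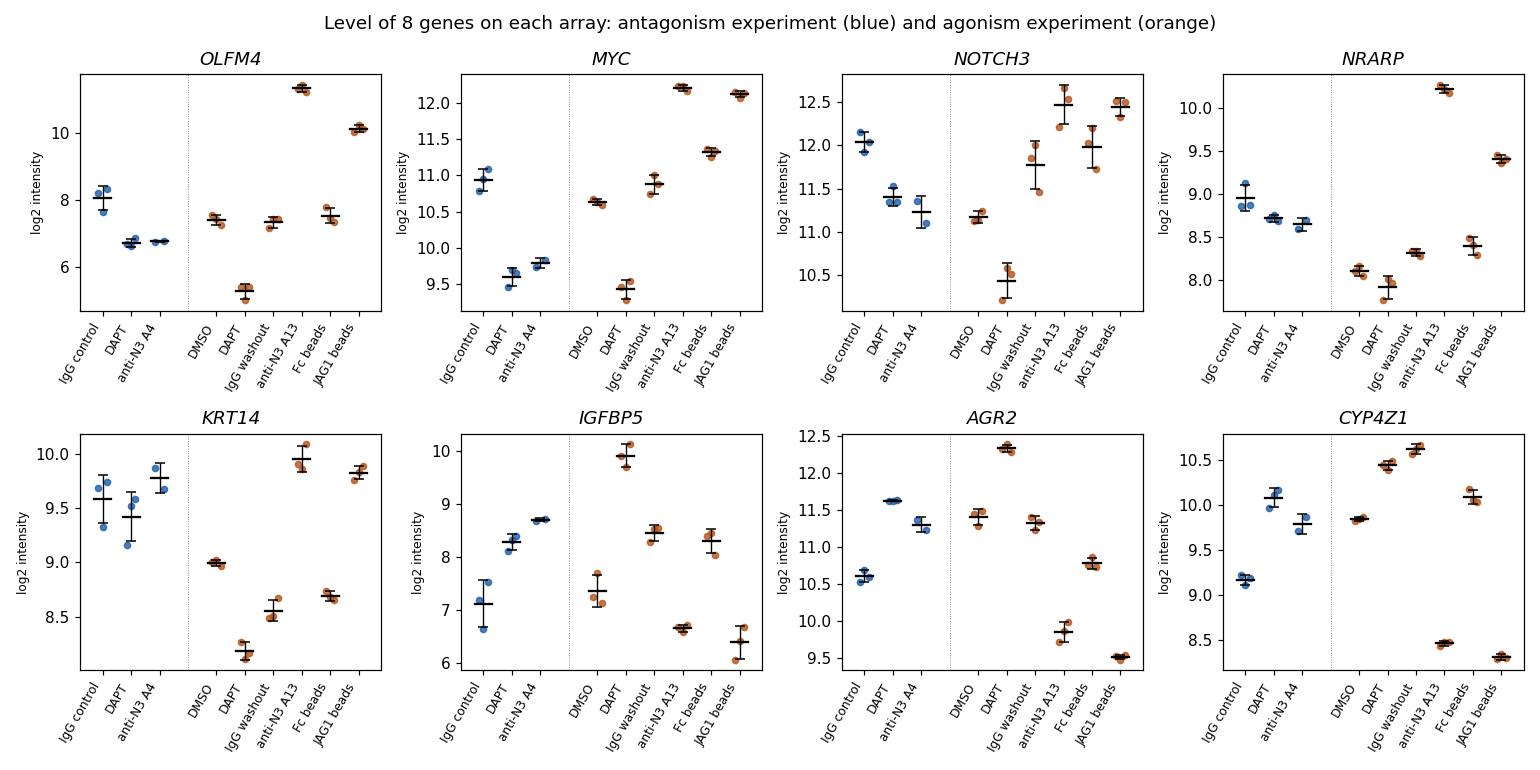
Log2 intensity (vertical axis) of 8 genes on each array, by treatment group (horizontal axis). Points are arrays, bars are group means and error bars are SDs; antagonism arrays are blue, agonism arrays orange, and levels are not comparable between the experiments. OLFM4 averaged 5.28 in continued DAPT, 7.34 after washout with IgG and 11.32 with A13, while CYP4Z1 averaged 10.44, 10.62 and 8.46.

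The first comparison asked what gamma-secretase inhibition changed in cells with their own Notch activity. DAPT lowered MYC, the growth-promoting transcription factor, by 1.34 ± 0.10 (log2 change ± SE; 3 arrays against 3). It also lowered OLFML3 (-1.25 ± 0.11), the secreted glycoprotein OLFM4 (-1.33 ± 0.16), CGA, the common subunit of glycoprotein hormones (-1.75 ± 0.25), the co-receptor NRP1 (-1.25 ± 0.17), and the serpins SERPINB4 (-1.18 ± 0.12) and SERPINB3 (-1.13 ± 0.15). AGR2, a protein of the endoplasmic reticulum (1.02 ± 0.07), MSMB (0.85 ± 0.08) and CRISP3 (0.91 ± 0.09) rose. The fatty acid hydroxylase CYP4Z1 rose by 0.91 ± 0.08, the signalling regulator RGS2 by 0.98 ± 0.09, CLCA2 by 1.06 ± 0.14 and IGFBP5, an insulin-like growth factor binding protein, by 1.17 ± 0.19. The adjusted p of these genes lay between 0.00216 for MYC and AGR2 and 0.0445 for IGFBP5.

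Among the 12 canonical Notch targets, HES1 (-0.51 ± 0.07) and NOTCH3 itself (-0.63 ± 0.10) fell with DAPT and 10 did not pass. NRARP, a feedback inhibitor of Notch, changed by -0.24 ± 0.09 (adjusted p = 0.286), and JAG1 by -0.64 ± 0.12 (adjusted p = 0.0781). The list as a whole was not called. Camera called its 6 members above the median level lower (adjusted p = 0.00105), which did not hold (adjusted p = 0.159 with an estimated correlation). Of the MYC and ribosome biogenesis list 1 of 25 members, MYC, fell, or 12 when adjusted over the list alone, with a median of -0.25. Of the G1/S list MCM10, a replication factor, fell by 0.55, or 16 of 29 members when adjusted over the list alone. Camera called both lists lower, and neither call held (adjusted p = 0.183 and 0.103 with an estimated correlation). Of the luminal markers AGR2 passed, or 7 higher and 1 lower of 26 when adjusted over the list alone (adjusted p = 0.262 with an estimated correlation).

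Together 70 of 19775 genes passed, 40 higher and 30 lower, and 2572 had an unadjusted p under 0.05. The count was fragile. It was 1198 without control 2, 11 without control 1, 35 without control 3, and 16, 12 and 17 without DAPT arrays 1, 2 and 3. With control 1 as the only control, which was then assumed to vary like the other groups, 28 genes passed, and 20 of these were among the 70. Of 28 named genes that passed, 9 kept their call with each array left out in turn, among them MYC, OLFML3, AGR2, CYP4Z1, CRISP3, MSMB and RGS2. OLFM4, IGFBP5, CGA, NRP1, HES1 and NOTCH3 each lost it at least 4 times.

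The NOTCH3 antibody A4 addressed the part of this response that runs through NOTCH3. OLFML3 fell by 1.33 ± 0.12, OLFM4 by 1.29 ± 0.18, MYC by 1.15 ± 0.11, NOTCH3 by 0.81 ± 0.11 and HES1 by 0.65 ± 0.08 (2 arrays against 3). The acute-phase protease inhibitor SERPINA3 (-0.96 ± 0.10), IER5 (-0.90 ± 0.09) and CAV1, the main protein of caveolae (-0.82 ± 0.11), fell as well. IGFBP5 rose by 1.59 ± 0.21, RGS2 by 1.02 ± 0.10, TP53INP2 by 0.88 ± 0.09, AGR2 by 0.69 ± 0.08 and the chemokine CCL20 by 0.61 ± 0.08. NRARP changed by -0.31 ± 0.10 (adjusted p = 0.342) and the other 9 canonical targets did not pass either; camera called the list lower, which did not hold (adjusted p = 0.122 with an estimated correlation). The G1/S list had a median of -0.22 with 0 of 29 members passing over all genes and 18 lower when adjusted over the list alone (adjusted p = 0.0902 with an estimated correlation). The G2/M list had a median of -0.21, with 0 of 30 passing and 11 lower over the list alone (adjusted p = 0.0708 with an estimated correlation).

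A total of 20 genes passed, 9 higher and 11 lower, and 1836 had an unadjusted p under 0.05. With either A4 array left out no gene passed, the lone array then being assumed to vary like the other groups. The count was 3, 96 and 6 without controls 1, 2 and 3, and 0 with only the 2 groups in the fit; every named gene lost its call at least once. With control 1 as the only control, under the same assumption, 10 genes passed, and 6 of these were among the 20.

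All 20 genes called with A4 moved the same way with DAPT. Of 9 called higher 7 were also called with DAPT (0.018 expected of independent lists), and of 11 called lower 10 were (0.017 expected). The changes correlated across genes at r = 0.539. Both effects were measured against the same 3 controls, and unchanged groups simulated against those controls gave a mean r of 0.448 (0.426 to 0.464 in 100 simulations). The covariance was 0.01205 against a simulated 0.006519. The simulation drew each gene and array independently, without the array-wide deviations that these controls show. It therefore does not show how far the observed values lie above chance. With 3 controls no split leaves 2 for each treatment, so part of the overlap may come from them. Compared directly, 0 genes differed between A4 and DAPT by limma, with 1628 at an unadjusted p under 0.05; the smallest p-values, none of which passed, belonged to CXCL8 (0.93 ± 0.15), FADS2 (0.76 ± 0.13), KRTAP9-4 (0.43 ± 0.08), PSD (-0.43 ± 0.08) and CCL20 (0.42 ± 0.08). NOTCH3 differed by -0.18 ± 0.11 and MYC by 0.19 ± 0.11. Camera called the NF-kB and cytokine list higher with A4 than with DAPT, with 0 of 25 members passing over all genes and 5 higher and 1 lower when adjusted over the list alone, and the call did not hold (adjusted p = 0.0987 with an estimated correlation). The absence of calls does not show that the 2 treatments act alike.

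In the agonism experiment continued DAPT was compared with DMSO, to show the baseline Notch activity of these plates. OLFM4 fell by 2.13 ± 0.12, MYC by 1.21 ± 0.07, NRP1 by 1.23 ± 0.09, the calcium-binding protein S100A3 by 1.26 ± 0.09, SERPINA3 by 1.14 ± 0.07 and the matrix protease MMP7 by 1.08 ± 0.09 (3 arrays against 3; adjusted p from 2.47e-08 to 2.17e-07). IGFBP5 rose by 2.56 ± 0.16, SCGB2A2, or mammaglobin, by 1.95 ± 0.15, PIP, the prolactin-induced protein, by 1.60 ± 0.11, CEACAM6 by 1.17 ± 0.08 and PSCA by 1.18 ± 0.08. Of the luminal markers 18 of 26 rose and 2 fell. AGR2 rose by 0.93 ± 0.07, the transcription factor FOXA1 by 0.75 ± 0.08 and LCN2 by 0.62 ± 0.07, while KIT fell by 0.61 ± 0.09 (adjusted p = 0.089 for the list with an estimated correlation). The basal keratins KRT14 (-0.81 ± 0.07) and KRT5 (-0.51 ± 0.08) fell, whereas the integrins ITGB4 (0.98 ± 0.09) and ITGA6 (0.57 ± 0.08) rose; 5 of 15 basal markers rose and 4 fell.

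HES1 (-0.39 ± 0.06), HEY1 (-0.26 ± 0.06) and NOTCH3 (-0.73 ± 0.14) fell among the 12 canonical targets, the other 9 did not pass, and NRARP changed by -0.19 ± 0.07 (adjusted p = 0.0563; for the list, adjusted p = 0.184 with an estimated correlation). Of the MYC and ribosome biogenesis list 14 of 25 fell and 0 rose, including MRTO4 (-0.63 ± 0.07), WDR12 (-0.60 ± 0.06) and NOC3L (-0.58 ± 0.07), all ribosome assembly factors (adjusted p = 0.0708 with an estimated correlation). Of the G2/M list 18 of 30 fell and 0 rose, among them HMMR, BIRC5 and CDK1 by 0.41 to 0.43 (adjusted p = 0.0987 with an estimated correlation). For the G1/S list, taken among genes above the median level, 6 of 29 rose and 9 fell, with a median of 0.005. Camera, which had called this list lower in the antagonism experiment, did not call it there (adjusted p = 0.241). The cell-cycle inhibitor CDKN1A rose by 0.80 ± 0.07. Of the immediate early and MAPK feedback list 10 of 28 rose and 0 fell, led by DUSP6 (1.06 ± 0.08), SPRED2 (0.87 ± 0.08) and DUSP4 (0.70 ± 0.07), which restrain MAP kinase signalling (adjusted p = 0.347 with an estimated correlation).

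In this comparison 4089 genes passed, 2446 higher and 1643 lower, of which 19 rose and 11 fell at least 2-fold. The balance depended on the scaling, since with median centring 1867 were higher and 2209 lower. The count was 2532 with only the 2 groups in the fit, 2630 without DAPT array 3, and 2585 and 2663 without DMSO arrays 1 and 3.

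The DAPT effects of the 2 experiments share no arrays. Of 40 genes called higher in the antagonism experiment 31 were called higher here (4.948 expected of independent lists), and of 30 called lower 21 were called lower (2.493 expected); 1 gene passed in opposite directions. Across all genes r was 0.268, and 0.158 without antagonism control 2. The difference of the 2 effects passed for 1211 genes. The increase of PIP in the agonism experiment was not matched in the antagonism experiment (difference -1.35 ± 0.16), and IGFBP5 rose less there (-1.39 ± 0.26). SCGB2A2 differed by -1.87 ± 0.20, but its mean levels of 4.82 to 4.94 in the antagonism groups lay below the lower quartile of every array there, where an effect may not show. CGA (-1.72 ± 0.26) and SERPINB3 (-1.08 ± 0.17) were lower by DAPT in the antagonism experiment relative to the agonism experiment. DEFB1 (1.08 ± 0.14) and MMP7 (0.90 ± 0.12), which fell in the agonism experiment, and RGS2 (0.89 ± 0.14) and MSMB (0.84 ± 0.14), which rose in the antagonism experiment, differed the other way. The difference did not pass for any canonical Notch target, NOTCH3 included (0.10 ± 0.19). The experiments also differed in plating density, prior exposure, the presence of IgG and the spread of log2 intensities. Changes of unlike size may partly reflect that spread. The direction of the 1211 depended on scaling (564 higher and 647 lower, or 908 and 389 with median centring). The count was 72 with only the 4 groups in the fit. It was 503, 509, 481 and 2828 without antagonism DAPT arrays 1 and 2 and controls 1 and 2, and 373, 357, 2398 and 326 without agonism DAPT array 3 and DMSO arrays 1, 2 and 3.

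The washout plates with control IgG asked what changed when DAPT was removed and no agonist was added. They differed from continued DAPT plates also in IgG and in the addition at 22 h, and these were not separated. Against continued DAPT, ID4, an inhibitor of differentiation factors, rose by 2.22 ± 0.12, OLFM4 by 2.06 ± 0.12, NRP1 by 1.49 ± 0.09, SERPINA3 by 1.49 ± 0.07, MYC by 1.45 ± 0.07 and NOTCH3 by 1.33 ± 0.14. PIP (-1.74 ± 0.11), SCGB2A2 (-1.51 ± 0.15), IGFBP5 (-1.46 ± 0.16) and AGR2 (-1.01 ± 0.07) fell. So did CYP1A1, a xenobiotic-metabolising enzyme (-2.13 ± 0.16), the water channel AQP3 (-2.12 ± 0.10) and DKK1, a Wnt inhibitor (-1.44 ± 0.10). AQP3 was lower and ID4 higher than in DMSO plates as well. Of the canonical targets 6 of 12 rose and 0 fell: NOTCH3, HES1 (0.67 ± 0.06), NRARP (0.41 ± 0.07), HEY2 (0.37 ± 0.09), HES4 (0.35 ± 0.08) and HEY1 (0.34 ± 0.06). The list call held with an estimated correlation (adjusted p = 0.0374), but not with that correlation among genes above the median level (adjusted p = 0.104, 6 members). JAG1 rose by 0.63 ± 0.07, NOTCH1 by 0.44 ± 0.09 and the cell-cycle gene CCND1 by 0.74 ± 0.08.

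On the same plates 14 of 26 members of the unfolded protein and amino acid stress list rose and 2 fell, including ATF3 (1.19 ± 0.12), the cystine transporter SLC7A11 (1.11 ± 0.11), CHAC1 (1.09 ± 0.10) and SESN2 (0.87 ± 0.10), targets of ATF4 signalling (adjusted p = 0.122 with an estimated correlation). Of the MYC and ribosome list 10 of 25 rose and 0 fell (adjusted p = 0.158 with an estimated correlation), and of the immediate early list 13 of 28 rose and 1 fell (adjusted p = 0.222 with an estimated correlation). Altogether 1932 genes passed, 821 higher and 1111 lower. The count was 1054 without DAPT array 1, 1101 without IgG array 2, 1141 with the 2 groups alone and 1203 without probe sets ending in _x_at or _s_at. HEY2 lost its call without IgG array 1 or DAPT array 1, and HES4 without DAPT array 1.

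Washout plates were also compared with DMSO plates. No difference passed for OLFM4 (-0.07 ± 0.12, adjusted p = 0.711), AGR2 (-0.08 ± 0.07, adjusted p = 0.462) or PIP (-0.14 ± 0.11, adjusted p = 0.351), which had all changed with DAPT, while MYC was higher by 0.24 ± 0.07. Among the canonical targets NOTCH3 (0.60 ± 0.14) and HES1 (0.28 ± 0.06) were higher and the others apart from NRARP did not pass; NRARP (0.22 ± 0.07) passed, but not with median centring or repeated quantile normalization, nor without IgG array 1 or 2 or DMSO array 1 or 3. ID4 was higher by 1.30 ± 0.12, LBH by 1.47 ± 0.16, CTH, an enzyme of cysteine synthesis, by 1.39 ± 0.12 and CCN1, a matrix signalling protein, by 1.14 ± 0.08. IGFBP5 was still higher (1.10 ± 0.16). The nuclear non-coding RNA MALAT1 (-1.95 ± 0.29), AQP3 (-1.88 ± 0.10), IGFL1 (-1.63 ± 0.09), OLFML3 (-1.38 ± 0.09) and CAV1 (-0.99 ± 0.08) were lower. Of the immediate early list 22 of 28 members were higher and 0 lower, with JUN at 0.87 ± 0.10 and DUSP1 at 0.75 ± 0.14 (adjusted p = 0.0987 with an estimated correlation). Of the stress list 17 of 26 were higher and 2 lower, with TRIB3 at 1.01 ± 0.07 and CHAC1 at 0.99 ± 0.10 (adjusted p = 0.152 with an estimated correlation). Of the luminal markers 14 of 26 were higher and 0 lower, with CLDN3 at 0.59 ± 0.08 and GATA3 at 0.48 ± 0.07 (adjusted p = 0.215 with an estimated correlation). Of the G2/M list 11 of 30 were lower and 1 higher (adjusted p = 0.347 with an estimated correlation). In all 6049 genes passed, 3548 higher and 2501 lower, or 2602 and 2996 with median centring. The DMSO plates differed from the IgG plates in prior DAPT, IgG and the addition at 22 h, so the sources of these changes are not separated.

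The agonist antibody A13 was compared with control IgG, both after washout. OLFM4 rose 15.8-fold (3.98 ± 0.12 on the log2 scale, adjusted p = 2.8e-13; 3 arrays against 3). GAS1 rose by 1.99 ± 0.10, FAM43A by 1.96 ± 0.12, NRARP by 1.90 ± 0.07, the transcription factor FOXQ1 by 1.47 ± 0.09, MYC by 1.33 ± 0.07 and the retinaldehyde dehydrogenase ALDH1A1 by 1.32 ± 0.08. The genes that fell included CYP4Z1 (-2.16 ± 0.06), SCGB2A2 (-2.12 ± 0.15), GLYATL2 (-1.91 ± 0.07), the mucin-like MUCL1 (-1.81 ± 0.08), IGFBP5 (-1.80 ± 0.16), the fibrinogen chain FGG (-1.80 ± 0.07), the prostaglandin E synthase PTGES (-1.71 ± 0.06) and DKK1 (-1.71 ± 0.10).

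Of the canonical Notch targets 7 of 12 rose with A13 and 0 fell (adjusted p = 0.0335 with an estimated correlation, but 0.104 for the 6 members above the median level). Besides NRARP these were NOTCH3 (0.70 ± 0.14), HEY1 (0.50 ± 0.06), HES4 (0.49 ± 0.08), HES2 (0.41 ± 0.08), HEY2 (0.34 ± 0.09) and HES1 (0.33 ± 0.06), and HEY2 lost its call without A13 array 3 or IgG array 2. JAG1 rose by 1.08 ± 0.07 and NOTCH1 by 0.52 ± 0.09. The MYC and ribosome list had 19 of 25 members up and 0 down, with LYAR at 0.70 ± 0.08, NOC3L at 0.64 ± 0.07 and WDR43 at 0.60 ± 0.07 (adjusted p = 0.0335 with an estimated correlation, but 0.104 among genes above the median level). CCND1 rose by 0.88 ± 0.08 and E2F2 by 0.60 ± 0.07, though 3 of 29 members of the G1/S list rose and 1 fell (adjusted p = 0.54 with an estimated correlation).

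Epithelial markers moved with A13 in both directions. Of the luminal markers 17 of 26 fell, led by AGR2 (-1.47 ± 0.07), LCN2 (-1.06 ± 0.07) and MUC1 (-0.95 ± 0.07), and 1, the receptor tyrosine kinase KIT, rose (1.07 ± 0.09; for the list, adjusted p = 0.0867 with an estimated correlation). Of the basal markers 7 of 15 rose and 3 fell, with KRT14 (1.40 ± 0.07), KRT5 (1.30 ± 0.08), VIM (0.94 ± 0.19) and KRT16 (0.83 ± 0.07) rising most (adjusted p = 0.306 with an estimated correlation). Interferon response genes fell, 12 of 29 with 0 rising, including BST2 (-0.69 ± 0.09), the immunoproteasome subunit PSMB9 (-0.64 ± 0.07), OAS1 (-0.62 ± 0.06) and ISG15 (-0.62 ± 0.07). This call held with an estimated correlation (adjusted p = 0.0383), but not for the 15 members above the median level (adjusted p = 0.229). In the immediate early and MAPK feedback list 9 of 28 rose and 5 fell, DUSP6 (-0.88 ± 0.08) and DUSP4 (-0.61 ± 0.07) falling and SPRY2 (0.74 ± 0.10) and IER3 (0.69 ± 0.06) rising (adjusted p = 0.624 with an estimated correlation). Altogether 2908 genes passed, 1124 higher and 1784 lower, or 1483 and 1386 with median centring and 1646 and 1705 with repeated quantile normalization. Without probe sets ending in _x_at or _s_at, 1862 passed.

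**Figure D2:**
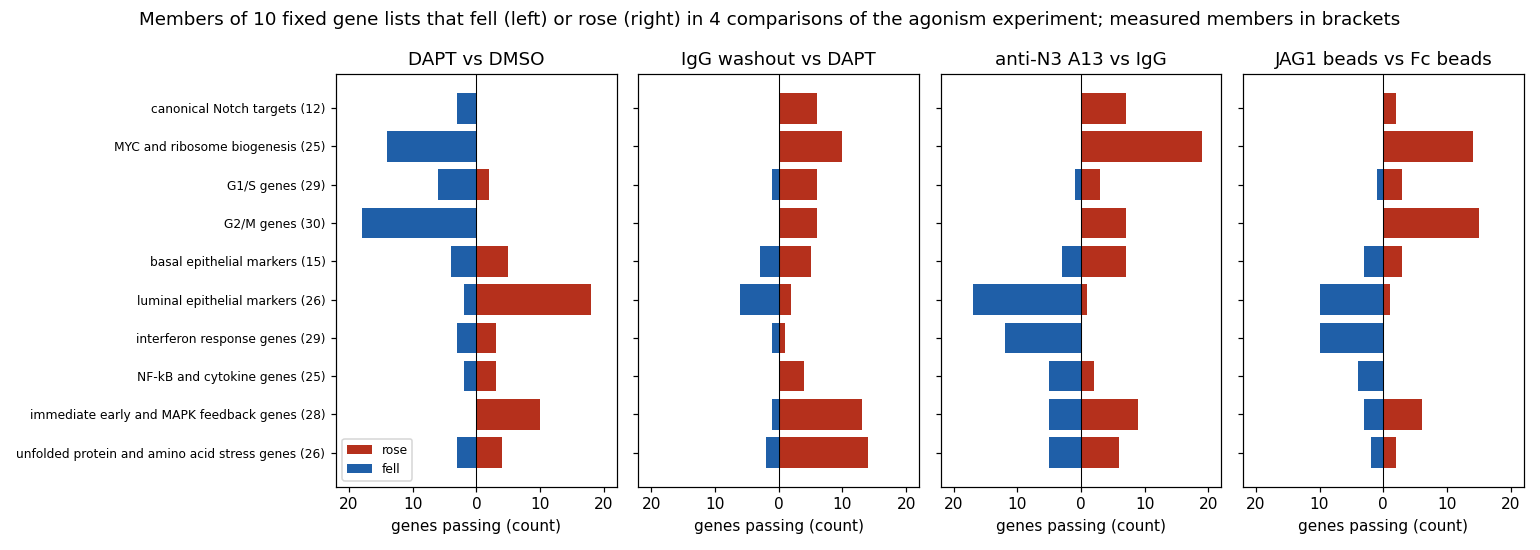
Number of members of 10 fixed gene lists (vertical axis, measured members in brackets) that rose (red, right) or fell (blue, left) in 4 comparisons of the agonism experiment (horizontal axis, count of genes). Of 26 luminal markers 18 rose and 2 fell with DAPT, 1 rose and 17 fell with A13, and 1 rose and 10 fell with JAG1, and none of these list calls held with an estimated correlation.

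JAG1-Fc beads, which present a ligand shared by several Notch receptors, were compared with Fc beads. OLFM4 rose by 2.59 ± 0.12, GAS1 by 1.42 ± 0.10, KRT14 by 1.14 ± 0.07, NRARP by 1.01 ± 0.07, ALDH1A1 by 0.94 ± 0.08, KRT5 by 0.93 ± 0.08 and MYC by 0.81 ± 0.07 (3 arrays against 3). IGFBP5 (-1.91 ± 0.16), CYP4Z1 (-1.78 ± 0.06), FGG (-1.41 ± 0.07), AGR2 (-1.27 ± 0.07), CLCA2 (-1.25 ± 0.08), SCGB2A2 (-1.18 ± 0.15) and MUCL1 (-1.16 ± 0.08) fell. Of the canonical targets 2 of 12 rose, NRARP and HES1 (0.22 ± 0.06), and HES1 lost its call in 5 of 6 fits with an array left out. NOTCH3 changed by 0.46 ± 0.14 (adjusted p = 0.0525), and the list was not called. Of the MYC and ribosome list 14 of 25 rose (adjusted p = 0.0708 with an estimated correlation), and of the G2/M list 15 of 30 rose, including CENPF (0.38 ± 0.07) and CENPE (0.36 ± 0.07; adjusted p = 0.0987 with an estimated correlation). In neither list did a member fall.

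Of the luminal markers 10 of 26 fell with JAG1 and 1, KIT (0.82 ± 0.09), rose (adjusted p = 0.0902 with an estimated correlation). Interferon response genes fell in 10 of 29 cases with 0 rising, including PSMB9 (-0.67 ± 0.07), GBP1 (-0.61 ± 0.10) and BST2 (-0.58 ± 0.09). The call held with an estimated correlation (adjusted p = 0.0374), but not for the 15 members above the median level (adjusted p = 0.159). Of the NF-kB and cytokine list 4 of 25 fell, the chemokines CXCL8 (-0.84 ± 0.15), CCL20 (-0.56 ± 0.09) and CXCL1 (-0.43 ± 0.09) and TNFAIP2 (-0.50 ± 0.09; adjusted p = 0.162 with an estimated correlation). In total 1604 genes passed, 587 higher and 1017 lower. The count was 897 without Fc array 2, 1059 without JAG1 array 1, 907 with the 2 groups alone and 968 without probe sets ending in _x_at or _s_at.

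**Figure D3:**
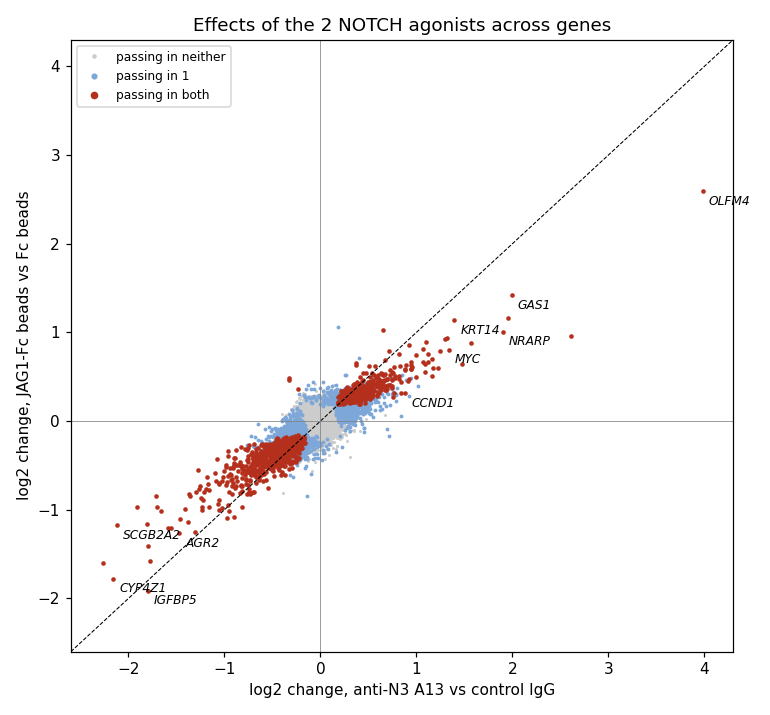
Log2 change with A13 against control IgG (horizontal axis) and with JAG1-Fc beads against Fc beads (vertical axis), 1 point per gene. Red genes passed in both, blue in 1, grey in neither, and the dashed line marks equal change; across genes r was 0.745, and OLFM4 changed by 3.98 and 2.59.

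The A13 and JAG1 effects share no arrays. Of 1124 genes raised by A13, 433 were also raised by JAG1 (33.365 expected of independent lists), and of 1784 lowered, 839 were also lowered (91.749 expected); 3 genes passed in opposite directions. Tested directly, the effects differed for 36 genes, 13 higher and 23 lower with A13 relative to JAG1. The difference was 1.39 ± 0.17 for OLFM4, 0.89 ± 0.10 for NRARP, 0.83 ± 0.13 for FOXQ1 and 0.53 ± 0.10 for MYC. It was -0.94 ± 0.10 for GLYATL2, -0.86 ± 0.08 for PTGES, -0.81 ± 0.09 for AKR1C2 and -0.80 ± 0.10 for HMOX1, a haem-degrading enzyme. The canonical targets as a list were raised more by A13, with a median difference of 0.21 and NRARP alone passing over all genes, or 4 of 12 when adjusted over the list alone (adjusted p = 0.0149 with an estimated correlation). The 2 agonists were set against different controls. MYC averaged 12.21 with A13 and 12.12 with JAG1-Fc beads, but 10.88 with IgG and 11.32 with Fc beads. In levels, its difference therefore lay mainly between the 2 controls, which does not show whether the agonists acted alike on MYC. Fc beads themselves raised HMOX1 and AKR1C2 relative to IgG (1.27 and 1.04). Both genes were higher by more with JAG1-Fc beads than with A13 (2.07 and 1.85). For them the rise with Fc beads made the difference of effects smaller and did not create it. The antibody and the beads were not matched in dose. The count of 36 was 28 without A13 array 3, 23 without Fc array 1, and between 10 and 17 with any other array left out. It was 8 without probe sets ending in _x_at or _s_at, and 12 with the 4 groups alone.

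The A13 effect also ran against the DAPT effect of the antagonism experiment, with which it shares no arrays. Of 40 genes raised by DAPT there, 35 fell with A13 (3.609 expected of independent lists), and of 30 lowered by DAPT, 24 rose with A13 (1.705 expected). In the same direction with both, 1 gene passed. Across all genes r was -0.462.

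The last comparison set the 2 control treatments after washout against each other. Fc beads raised GPNMB, a glycoprotein of lysosomes and melanosomes, by 1.86 ± 0.08 relative to control IgG, HMOX1 by 1.27 ± 0.07, the aldo-keto reductases AKR1C3 (1.21 ± 0.12), AKR1C2 (1.04 ± 0.06) and AKR1C1 (0.89 ± 0.07), CXCL8 by 1.03 ± 0.15 and MAFF by 0.86 ± 0.10. The 3 AKR1C genes are closely related in sequence, and their probe sets may not tell them apart. CLCA2 (-1.05 ± 0.08), MUCL1 (-0.98 ± 0.08), TFRC, the transferrin receptor (-0.79 ± 0.05), and AGR2 (-0.54 ± 0.07) fell. Of the immediate early list 13 of 28 rose and 0 fell, with EGR1 at 0.74 ± 0.09 and ATF3 at 0.62 ± 0.12 (adjusted p = 0.0383 with an estimated correlation, but 0.159 among genes above the median level). Of the NF-kB list 7 of 25 rose and 0 fell, with LIF at 0.81 ± 0.11 and RELB at 0.67 ± 0.09 (adjusted p = 0.0342 with an estimated correlation, but 0.104 among genes above the median level). None of the 12 canonical Notch targets passed, and MYC rose by 0.44 ± 0.07. There were 411 genes, 324 higher and 87 lower, or 340 and 200 with repeated quantile normalization. The count was 141 without IgG array 1, 144 without Fc array 1, 239 without Fc array 3, 249 without IgG array 3 and 61 with the 2 groups alone.

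Markers of other cell types served as controls. Of the fibroblast, leukocyte and endothelial lists, camera called the leukocyte list higher on washout against DAPT, where 1 of 11 members rose (CD14, 0.75 ± 0.08; adjusted p = 0.441 with an estimated correlation), and the fibroblast list lower with Fc beads, where 0 of 12 passed (adjusted p = 0.471 with an estimated correlation). CD14 then fell with A13 (-0.72 ± 0.08). The endothelial list was not called in any of the 11 comparisons.

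HES1 values rest on 1 of its probe sets. The gene's brightest probe set averaged 10.47 on the log2 scale over all arrays. Its probe set without an _s_at ending averaged 6.18 and changed by -0.12 on washout against DAPT and -0.05 with A13, neither passing. For GAS1 (7.92 and 6.33) the probe set without such an ending changed by -0.12 with A13 and -0.08 with JAG1, and for AKR1C2 (12.26 and 5.89) by -0.02 with Fc beads, none of which passed. Levels of different probe sets do not show which of them reads its gene better.

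Camera also called 6 of the remaining lists, none of them with an estimated correlation in any comparison. Each is given here for 1 comparison in which it was called. Cholesterol synthesis genes were called higher with DAPT in the antagonism experiment, with 0 of 19 passing and 7 when adjusted over the list alone (adjusted p = 0.183 with an estimated correlation). Hypoxia and glycolysis genes were called higher with DAPT in the agonism experiment, where 8 of 25 rose and 1 fell (adjusted p = 0.483 with an estimated correlation). TGF-beta and BMP targets were called higher on washout against DMSO, where 10 of 24 were higher and 1 lower (adjusted p = 0.358 with an estimated correlation). EMT and matrix genes were called higher on washout against DAPT, where 3 of 27 rose and 1 fell (adjusted p = 0.195 with an estimated correlation). Epidermal differentiation genes were called lower with JAG1, where 2 of 24 rose and 5 fell (adjusted p = 0.103 with an estimated correlation). Notch pathway components were called higher with Fc beads, where 1 of 33 rose (adjusted p = 0.347 with an estimated correlation), and the apoptosis and survival list was not called in any of the 11 comparisons.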

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

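The tests on other splits of the arrays, on uneven controls, on array-wide spread, on the return of Notch signalling and on control IgG were chosen or worded after the results they concern were seen. The tests on beads as such and on NRF2 activity were written down before their values were seen, for a pattern already noticed.

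The effect of DAPT differed between the experiments for 1211 genes, by a test of the difference itself. Of these, 934 passed in the agonism experiment and 26 in the antagonism experiment, 931 had the larger change in the agonism experiment, and 319 moved the same way in both. COMMD3 passed in opposite directions. It rose by 0.40 ± 0.06 in the antagonism experiment (adjusted p = 0.0363), changed by -0.22 ± 0.08 in the agonism experiment (adjusted p = 0.0408), and differed by 0.619 ± 0.096 (adjusted p = 0.00151); it was singled out after its values were seen. In 9 of 100 drawn splits as many genes differed as in the real one, which is included; the highest other split gave 2700. The 8 other splits each kept 1 of the 2 contrasts whole, and splits that mixed both gave at most 1102. With the agonism contrast turned around, 3162 genes differed. Splits with counts above the real one point to a structure of the samples, here the DAPT effects that both experiments hold. Mixing the arrays of a contrast reduces its DAPT effect, so the splits do not stand for equal effects in the 2 experiments, and whether chance can be excluded for the count of 1211 stays open. The experiments also differed in plating density and history, and these were not separated. Log2 intensities were spread less widely in the antagonism experiment (quartiles of 6.48 and 9.03 on control 1) than in the agonism experiment (5.56 and 8.50 on DMSO array 1). Part of the larger changes in the agonism experiment may come from this scale, which was not tested.

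The effects of A13 and JAG1 differed for 36 genes, again by a test of the difference. Of these, 30 moved the same way with both agonists and 31 changed more with A13. In 4 of 100 drawn splits, the real one included, as many genes differed, and the highest other split gave 1732. The 3 other splits kept 1 of the contrasts whole and so contain a whole agonist effect, which is a structure of the samples; splits that mixed both gave at most 1 gene. Mixing reduces the agonist effects, so these splits do not stand for equal effects of A13 and JAG1 either, and whether chance can be excluded for the count of 36 stays open. With the JAG1 contrast turned around, 4252 genes differed. The antibody and bead doses were not matched, so dose and agent cannot be separated here.

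For 7 comparisons of 3 arrays against 3 there were 10 splits, too few for a share under 0.05. For DAPT in the antagonism experiment 2 of the 10 splits gave at least the real count of 70, and the highest other gave 309. In the other 6 comparisons 1 of 10 splits, the real one, did so. The real counts were 4089, 1932, 2908, 1604 and 411, each with 0 as the highest other, for DAPT against DMSO, washout against DAPT, A13, JAG1 and Fc beads. Washout against DMSO gave 6049, with 1 as the highest other.

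The split with 309 genes put DAPT arrays 1 and 2 with control 2 and the other controls with DAPT array 3, which points to a structure of the antagonism arrays. Controls 2 and 3 lay at opposite ends of the first principal component (0.64 and -0.57, 41.3% of variance), and their upper quartiles of log2 intensity were 8.91 and 9.09. Uneven controls as the source of the 70 DAPT genes were argued against by the agonism experiment, which shares no array with this one: 94.3% of the 70 (66 genes) moved the same way there, against 52.9% of all genes. A spread across arrays that follows the upper quartile stays open. With the upper quartile as a covariate 100% of the 70 passed, and 674 genes passed in all. This test cannot decide, because the upper quartiles of the DAPT arrays all lay between those of controls 2 and 3. A covariate that differed so little between the groups could hardly remove a call. What made the arrays differ stays open, since the labels give no batch, and an effect of gamma-secretase inhibition stays among the open explanations as a hypothesis.

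Fc beads differed from control IgG for 411 genes. Beads as such, whatever they carry, are a candidate explanation that met its test. Between JAG1-Fc beads and A13, which share no array with the first comparison, 94.9% of the 411 (390 genes) had the same sign, against 64.2% of all genes, and 256 passed. GPNMB changed by 1.86 ± 0.08 and 1.97 ± 0.08 in the 2 comparisons, HMOX1 by 1.27 ± 0.07 and 2.07 ± 0.07, and TFRC by -0.79 ± 0.05 and -0.91 ± 0.05. CXCL8 changed by 1.03 ± 0.15 and by 0.32 ± 0.15, the latter not passing (adjusted p = 0.254). Array-wide spread stays open for part of the pattern: with the upper quartile as a covariate 53.8% of the 411 passed and 251 genes passed in all. Of the 411, 0 changed sign, and a lost call alone does not show that the spread made the change. Soluble protein against bead, and IgG against Fc, differ together in this design, and no bead without protein was included.

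In the washout plates with IgG 14 genes of the stress list were higher than in both DMSO and continued DAPT plates, by medians of 0.58 and 0.61. Both medians use the same IgG arrays and follow from the choice of genes, which were those passing as higher in both comparisons. Control IgG as such stays open. The genes were higher in Fc bead plates than in IgG plates, by a median of 0.409 (8 rose and 0 fell), but they were also higher with JAG1-Fc beads than with A13 (median 0.332, 9 rose and 0 fell), so bead plates are no baseline without IgG for them. A protein with an Fc part was present on both. A return of Notch signalling stays open too. Were Notch activity the driver, the genes would have been lower in DAPT than in DMSO plates, and their median change there was 0.012, with 1 rising and 3 falling. That value met the bound first set against this explanation, but by less than the SD of the genes' changes (0.215). Of the 14, 6 rose with A13 (median 0.255) and 2 with JAG1 (median 0.164), and 0 fell with either. The readings of this test and of the one on control IgG were changed after their values were seen. Washout itself, and the addition of DMSO or DAPT at 22 h to the 2 groups set against IgG, were not tested, since no groups differed in these alone.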

How the results depend on the processing

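The upper quartile as a covariate, and leaving out antagonism controls 2 and 3 together, were chosen after seeing the data; the other alternatives were planned. Counts are genes passing. Where fewer arrays or genes were used the change follows partly from that; otherwise the cause was not tested. No paired analysis was possible because the labels give no replicate numbers.

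For DAPT in the antagonism experiment (70) the count was 192 with repeated quantile normalization, 109 with median centring, 261 among genes above the median level, 41 without probe sets ending in _x_at or _s_at, 306 with a trended and robust variance, 7600 with array weights, 18 with only the compared groups and 1014 with all 26 arrays in 1 fit. It was 674 with the covariate and 28, with 20 of the 70 among them, without controls 2 and 3. For A4 (20) the counts were 56 with quantile normalization, 108 among bright genes, 144 with trended variance, 1787 with array weights, 0 with the compared groups and 441 with all arrays. They were 266 with the covariate and 10, with 6 of the 20 among them, without controls 2 and 3. In these fits the control arm was control 1 alone, assumed to vary like the other groups, so they do not show whether uneven controls lie behind the calls. A4 against DAPT (0) gave 1 with array weights, 2 with all arrays and 1 with the covariate. The fit of array weights did not fully converge in some comparisons.

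In the agonism experiment the compared groups alone gave 2532 genes for DAPT against DMSO (4089), 1141 for washout against DAPT (1932), 907 for JAG1 (1604), and 61 for Fc beads (411). Without probe sets ending in _x_at or _s_at the counts were 1203 for washout against DAPT, 1862 for A13 (2908), 968 for JAG1 and 208 for Fc beads. Fc beads gave 843 among bright genes, 761 with trended variance and 251 with the covariate. Washout against DMSO (6049) stayed within 1.5 times under every alternative run.

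The difference of agonist effects (36) was 70 among bright genes, 22 with the mean of probe sets, 8 without _x_at or _s_at, 79 with trended variance, 60 with array weights, 12 with the compared groups and 23 with all arrays. The difference of DAPT effects (1211) was 1993 among bright genes, 514 without _x_at or _s_at, 1840 with trended variance, 72 with the compared groups and 800 without controls 2 and 3, with the same lone control. Gene list calls (75) were 8 with an estimated correlation, and 61 among genes above the median level, or 1 there with an estimated correlation.

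Among genes above the median level the correlations were 0.703 for A4 and DAPT (0.539), 0.867 for A13 and JAG1 (0.745), 0.361 for DAPT in both experiments (0.268) and -0.582 for DAPT and A13 (-0.462).

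Leaving out each array in turn gave 11 to 1198 genes for DAPT in the antagonism experiment, 0 to 96 for A4 and 0 for A4 against DAPT. It gave 2585 to 4975 for DAPT against DMSO, 1054 to 1793 for washout against DAPT, 4462 to 6682 for washout against DMSO, 2116 to 2611 for A13, 897 to 1447 for JAG1 and 141 to 361 for Fc beads. The difference of agonist effects ranged from 10 to 28 and that of DAPT effects from 326 to 2828. The correlations ranged from 0.443 to 0.666 for A4 and DAPT, 0.691 to 0.746 for A13 and JAG1, 0.158 to 0.3 for DAPT in both experiments and -0.472 to -0.395 for DAPT and A13. Where 1 A4 array was left it was assumed to vary like the other groups.

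Among results passing in the main fit or in the alternative, directions changed for 27 values of 14 named genes. All were with other probe sets or with the mean of a gene's probe sets, and no value with a changed direction passed. Without _x_at or _s_at probe sets HES1 changed by 0.105 with A4, 0.057 with DAPT against DMSO, -0.116 on washout against DAPT, -0.059 on washout against DMSO, -0.048 with A13 and -0.076 with JAG1. GAS1 changed by -0.123 with A13 and -0.076 with JAG1, and CXCL2 by 0.033 with DAPT against DMSO, -0.219 with A13 and -0.285 in the difference of agonist effects. GINS2 changed by 0.005 with DAPT against DMSO and 0.081 on washout against DMSO. On washout against DAPT CENPF changed by -0.535, THBS1 by 0.135, GADD45B by -0.037 and MCL1 by -0.193. On washout against DMSO CHAF1A changed by -0.029 and FN1 by -0.063. With A13 FN1 changed by 0.083 and ASNS by -0.012, with JAG1 THBS1 by -0.095 and IFI44 by 0.057, and AKR1C2 by -0.017 with Fc beads and 0.016 in the difference of agonist effects. With the mean of probe sets CENPF changed by -0.051 and AURKB by -0.004 on washout against DAPT. Each gene's own probe set was its brightest by choice. Probe sets differ in affinity and there were no detection calls, so levels do not show which probe set reads the gene better.

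Other named results that passed in the main fit kept their direction, and turns among results passing in neither fit were not counted. Of those passing, 117 lost their call with only the compared groups, 67 with the mean of probe sets, 60 without _x_at or _s_at, 29 with all arrays, 12 with median centring, 7 with quantile normalization, 4 with trended variance and 4 with array weights. Scaling moved the median of all genes by under 0.1 in each comparison. It changed the balance of higher and lower genes from 2446 and 1643 to 1867 and 2209 for DAPT against DMSO with median centring.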

Other observations

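The tests in this part were chosen after the data were examined, and the bound for the NRF2 list was written before its values were seen.

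A candidate explanation for the genes higher with beads is activity of NRF2, the transcription factor of the oxidative stress response. A list of 22 NRF2 targets was written without HMOX1 and the AKR1C genes, which had prompted the idea, and 20 were measured. Their median change between Fc beads and IgG was 0.205, with 8 rising and 0 falling (camera p = 4.16e-14, and p = 0.000621 with an estimated correlation). TXNRD1 rose by 0.56 ± 0.06, SQSTM1 by 0.52 ± 0.07, GCLC by 0.47 ± 0.07 and NQO1 by 0.30 ± 0.05. Between JAG1-Fc beads and A13 the median was 0.40, with 15 rising and 0 falling (p = 6.22e-05 with an estimated correlation). This is consistent with NRF2 activity in bead plates, as a hypothesis found and tested on the same experiment. Beads in place of soluble antibody cannot be separated from other differences between these plates.

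DMSO plates, the plates of the agonism experiment without prior DAPT, differed from the mean of the other 5 groups for 7536 genes, 3071 higher and 4465 lower in DMSO. This balance was not repeated with other scalings, and in the comparisons of DAPT and of washout with DMSO it depended on the scaling. AQP3 (1.91 ± 0.08) and MALAT1 (1.30 ± 0.22) were among the higher genes, and LBH (-1.78 ± 0.12), CTH (-1.61 ± 0.09), ID4 (-1.38 ± 0.09) and ATF3 (-1.35 ± 0.09) among the lower. The mean of the other 5 groups hides differences among them. AQP3 was also higher, and ID4 and ATF3 also lower, in continued DAPT than after washout with IgG. These genes therefore do not mark the plates without prior DAPT alone. MALAT1 averaged 12.02 in DMSO (SD 0.57), 11.26 in continued DAPT (SD 0.27) and 10.07 after washout with IgG (SD 0.25). It averaged 10.74 with A13, 10.73 with Fc beads and 10.80 with JAG1-Fc beads.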
